A study of Mus musculus with 6 samples.

How the data were processed

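RNA was taken from about 100 mg of fresh tumour in 3 DKO and 3 TKO mouse osteosarcomas, made into libraries after selection on oligo(dT) beads and sequenced on an Illumina HiSeq, per the labels' protocols. The authors deposited counts of reads per gene, written by STAR's gene counting for each library, together with a table of the whole series. STAR 2.6.1 and the mm10 build are named per the submitters' processing notes; the annotation release is not given in the sources used here. The deposited counts are whole numbers and carry no normalization. Of the 3 count columns in each library's file (reads on either strand, and on each strand alone), the first was used, since the labels' protocols describe a second strand made without a strand mark. The column for the first strand held 50.2 to 51.3% of the stranded counts, so overlapping and antisense genes cannot be told apart. The series table held the same values, with 0 genes that differed.

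Each file listed 56196 genes and 4 lines of reads assigned to no gene, which were left out of library sizes and tests. Unmapped reads were 2.53 to 3.2% of the reads in a file, reads at several places 3.94 to 4.7%, reads in no gene 5.33 to 9.3% and reads in more than 1 gene 5.1 to 6.53%. Gene IDs were matched to symbols through GENCODE M21 (GRCm38, the same assembly as mm10), without the version number. This matched 55154 IDs, and the 1042 unmatched IDs held at most 0.086% of the counts of any library. The 213 IDs that share a symbol with another ID were kept apart by ID. Positions of genes come from the same annotation. Depth was 17063231 to 22488819 gene counts per library. A count of 0 allows up to 3 counts, and folds against a group at 0 were computed against 3 counts over the whole group. For genes with 1 to 3 counts in a group, the ratio is given with an exact 95% counting interval. Reads were not marked with molecular identifiers, so intervals and floors cover counting error only. No pair of libraries agreed within sampling noise.

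Genes were kept by filterByExpr on the groups (minimum count 10), leaving 15361, and scaled by TMM factors. The 2 groups were compared by edgeR's quasi-likelihood test with robust dispersion and no covariate (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of genes come from this test unless another tool is named. CPM values are counts-per-million of the effective library size (total times TMM factor), and the SE of a log2 fold change was taken from the fold and the F statistic. Lists were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 34 lists with 5 or more measured members, with camera under an estimated correlation and fry as alternatives. The level of a list in a tumour is the mean log2 CPM of its members, compared by an exact two-sided permutation test over 20 assignments, which cannot go below 0.1.

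The groups, tests, gene lists, rule for named genes and alternatives other than those named below as added were set before the data were examined. There were 36 lists: cell cycle and tumour lists (SKP2 partners and substrates, G2/M, E2F targets, E2F1-linked apoptosis, p53 targets, MYC targets, ribosomal proteins), leukocyte lists (macrophage core, M2-like, M1-like, chemoattractants, T and NK, B and plasma, neutrophil, dendritic, mast), immune function lists (MHC class I and II, interferon-stimulated, checkpoint, complement), tissue lists (endothelial, pericyte, fibroblast, osteoblast, chondrocyte, osteoclast, muscle, adipocyte, erythroid, skin) and state lists (matrix, hypoxia and glycolysis, immediate early, mitochondrial). The genotype genes and the mast cell list, which had 3 measured members, were not tested as lists. Genes were named by rule: Skp2, Rb1 and Trp53; the 12 highest and 12 lowest log2 fold changes among genes past 0.05 with a mean log2 CPM of at least 1 and groups that did not overlap, leaving out predicted and clone names and variable, diversity and joining segments of antigen receptors; and up to 4 members of each list with the smallest p. Some genes that this rule names are not reported here. Other members were named after their values were seen: Irf5, Plk2 and Gadd45a, as were the genes in the plot of bone and myogenic genes.

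The test was tried on simulated data, 5 runs on 15361 genes with the means and library sizes of the TKO against DKO comparison. It recovered 10% of 4-fold and 66.6% of 16-fold changes with 4.8 false calls per run. DESeq2 recovered 46.6% and 91.6% with 90.4 false calls per run. Camera called the planted list of 20 genes in 5 of 5 runs and the flat list in 0. Genes were drawn independently in these runs, whereas the correlation estimated in the real data was 0.69 for the muscle list and 0.91 for G2/M. The runs therefore do not show how often camera with a preset correlation of 0.01 makes false calls on correlated lists. Alternatives were RLE size factors, library totals, DESeq2 1.42.0, limma-voom, no filter, at least 1 CPM in 3 samples, a replicate block, sex as a covariate, counts of the other strand column, dispersion without robust fitting, leaving out muscle, erythroid and mitochondrial genes, a log2 fold threshold of 1, other list tests and leaving out each library. Restricting the test to genes with at least 1 CPM in a library of each group was added after seeing the data, as were DESeq2, limma-voom and the list tests with an estimated correlation without each library, list members adjusted over the list alone without each library, and p-values of the full test adjusted over the restricted genes. The labels give no batch or date, so a batch that follows the groups could not be examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.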

Results

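Gene expression was measured by sequencing of polyadenylated RNA in 6 mouse osteosarcomas that arose in bone lineage cells lacking the tumour suppressors Rb1 and Trp53. Both genes carried loxP sites and were cut by a Cre recombinase under control of Osx1 (Sp7), a transcription factor of osteoblast precursors. In 3 tumours Skp2 was intact (double knockout, DKO) and in 3 it was deleted in the germ line (triple knockout, TKO). SKP2 is the substrate-recognition subunit of an SCF ubiquitin ligase that targets cell cycle inhibitors such as p27 for degradation. Each group held 1 male tumour, replicate 1, and 2 female tumours, replicates 2 and 3. Total gene counts were 21581482, 18707108 and 17063231 in DKO1, DKO2 and DKO3 and 22488819, 21299187 and 20002918 in TKO1, TKO2 and TKO3. The labels do not state that each tumour came from a different mouse, so p-values measure the spread between these samples.

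Skp2 transcripts matched the labels in all 6 libraries. Skp2 (ENSMUSG00000054115.11, chromosome 15, 9111985 to 9155425, GRCm38) had 20, 64 and 46 counts in DKO1, DKO2 and DKO3 and 0 counts in each TKO library. It was at least 49.4-fold lower in TKO, from 2.33 ± 1.19 counts-per-million (CPM; SD, n = 3) in DKO, with an adjusted p of 0.0284 in edgeR's quasi-likelihood test. The Skp2 call was lost under the replicate block (0.105) and without DKO1 (0.0779), DKO2 (0.111), DKO3 (0.118), TKO2 (0.0605) or TKO3 (0.0622). Rb1 (ENSMUSG00000022105.6, chromosome 14, 73183673 to 73325822) was 3.06-fold higher in TKO, with 62.9 ± 25.2 CPM against 20.6 ± 2.37 CPM in DKO (SD, n = 3; log2 fold change 1.61, SE 0.35, adjusted p = 0.0419). That call was lost by limma-voom (0.0511), under the replicate block (0.101) and with genes near absent in either group left out (0.0737). It was also lost without DKO1 (0.129), DKO2 (0.165), DKO3 (0.148), TKO2 (0.0769) or TKO3 (0.0602). Trp53 (ENSMUSG00000059552.13, chromosome 11, 69580359 to 69591873) had 22.7 ± 14.7 CPM in TKO and 6.75 ± 0.674 CPM in DKO, a log2 fold change of 1.75 (SE 0.57) that did not pass the threshold (adjusted p = 0.115), but passed by DESeq2 (0.0315) and without TKO1 (0.0174). Both floxed genes were targeted alike in the 2 groups and only part of each is removed, so these gene-level counts do not check their deletion.

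The main comparison asked how transcription differs between SKP2-null and SKP2-intact tumours. The DKO libraries held almost no blood RNA, with 12 haemoglobin counts in all against 37868 in TKO. Genes called higher or lower in TKO below therefore differ between the libraries, and genotype was not separated from cell content. Of 15361 genes tested, 1131 changed, 751 higher and 380 lower in TKO, and in every one of them the 3 TKO values lay on one side of the 3 DKO values. Over all tested genes 32.9% separated the groups in this way, against 10% by chance. Lists of macrophage, plasma cell, red cell, vessel and muscle genes were higher in TKO and the list of hypoxia and glycolysis genes was lower: 22 of 34 lists passed camera, 16 higher and 6 lower, 0 of them with an estimated correlation. By fry 15 lists were higher and 1 lower, of which E2F1-linked apoptosis did not pass camera. Of the 751 higher genes, 487 (64.8%) lay under 1 CPM in every DKO library, while 79 of the 380 lower genes (20.8%) lay under 1 CPM in every TKO library. Of the 1131 genes, 561 (261 higher, 300 lower) had at least 1 CPM, here of plain library totals, in at least 1 library of each group. When only such genes were tested, 158 of the 561 passed (74 higher, 84 lower), and all 561 kept their sign and an unadjusted p under 0.05. TKO1 stood apart from the other TKO tumours: across genes, its log2 CPM correlated with TKO2 and TKO3 at 0.837 and 0.814, while TKO2 and TKO3 correlated at 0.925 and the DKO pairs at 0.95 to 0.967. On the second principal component, which carried 22.1% of the variance after 56.9% on the first, TKO1 lay at -143.86 and TKO2 and TKO3 at 48.88 and 68.1. The count of changed genes depended on which libraries entered: edgeR called 39 genes without DKO1, 2 without DKO2, 0 without DKO3 (3017 at an unadjusted p under 0.05; 2203 by DESeq2 and 0 by limma-voom), 2385 without TKO1, 475 without TKO2 and 331 without TKO3. Without DKO3 the smallest adjusted p in edgeR was 0.0545, all 1131 genes kept their sign, and 179 list members in 23 lists passed when adjusted over the list alone.

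The steepest increases in TKO were in genes that were silent or nearly silent in DKO. The chains of complement C1q, which macrophages secrete, were absent from all 3 DKO libraries. C1qa, C1qb and C1qc, neighbours on chromosome 4 (136880129 to 136898803), reached 258 ± 129, 255 ± 93.7 and 185 ± 72.4 CPM in TKO (SD, n = 3), at least 4750-, 4720- and 3410-fold above the DKO floor of 3 counts over the group (adjusted p = 0.0111 for each). Laptm5, a lysosomal protein of haematopoietic cells (chromosome 4, 130913125 to 130936141), had 1 count in DKO and 282 ± 142 CPM in TKO, a ratio of 15400 (95% counting interval 2760 to 608000). The MHC class II chain H2-Aa (chromosome 17, 34282744 to 34287823) rose at least 2110-fold, the immunoglobulin A constant region Igha at least 2150-fold and the beta-globin Hbb-bs at least 5910-fold, with 618, 39.1 and 232 CPM in TKO1, TKO2 and TKO3. Hbb-bs shares sequence with Hbb-bt, and reads that match several places were left out, so both may be undercounted. The muscle genes Myh4, Tnni2 and Myh1, coding for fast myosins and a fast troponin, rose with ratios of 61700 (11100 to 2440000), 10300 (1850 to 407000) and 9690 (1740 to 383000), and Pdlim3, a muscle Z-disc gene, rose at least 2000-fold. TKO2 carried most of the rise in Myh4 (14.6, 3110 and 279 CPM in TKO1, TKO2 and TKO3), Tnni2 (39.8, 430 and 95 CPM) and Pdlim3 (47.6, 253 and 22.9 CPM). Myh1 and Myh4 are similar neighbours on chromosome 11. The osteocyte matrix gene Dmp1 rose at least 2510-fold, from 0 counts in DKO to 16.4, 251 and 152 CPM in TKO1, TKO2 and TKO3.

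**Figure D1:**
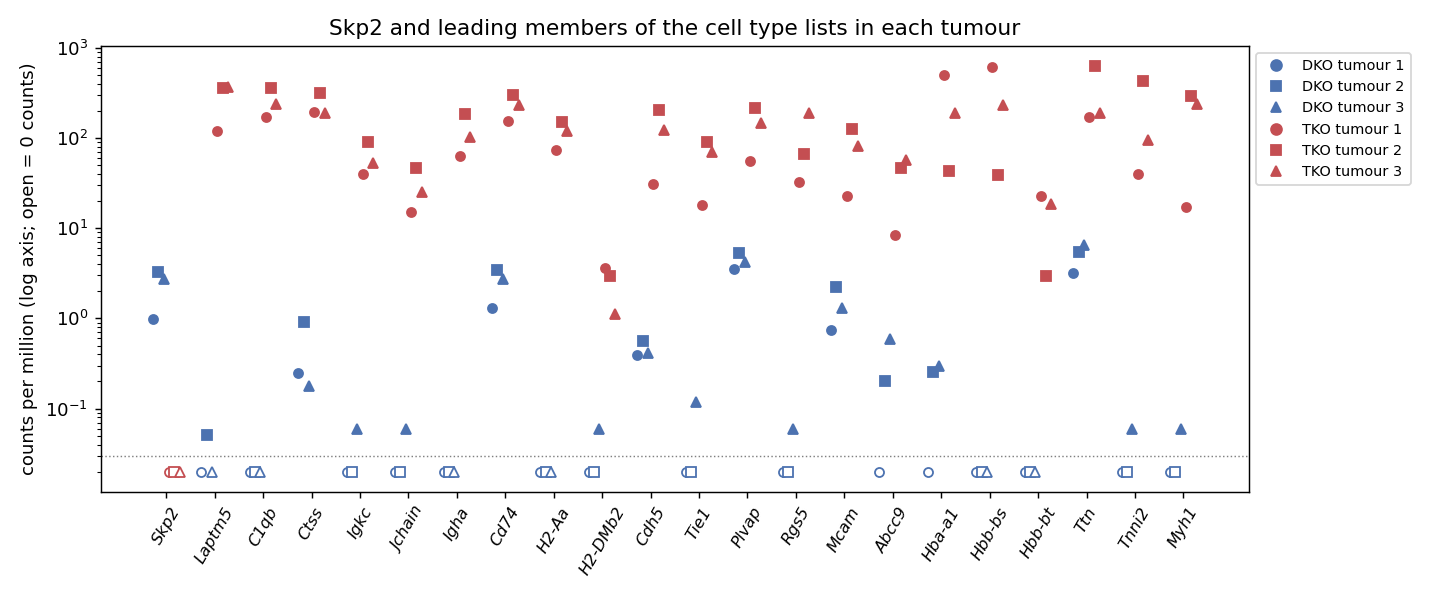
Counts-per-million (log axis) of Skp2 and of the 3 members with the smallest p of 7 cell type lists in each of the 6 tumours, with open symbols below the dotted line for 0 counts. Skp2 is at 0 in all 3 TKO tumours, and C1qb, Igha, H2-Aa, Hbb-bs and Hbb-bt are at 0 in all 3 DKO tumours.

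Macrophage genes rose together in TKO tumours. Of 26 measured core macrophage markers, 22 rose over all genes tested (24 adjusted over the list alone) and none fell, with a median log2 fold change of 8.43, or 8.27 with genes at 0 set to their bound. Adjusted over the list alone, 24 macrophage markers also rose without DKO3. The list level, the mean log2 CPM of its members, was 6.20 ± 0.68 in TKO and -1.09 ± 0.27 in DKO (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Beside Laptm5, C1qb and C1qc, the lysosomal protease Ctss rose from 0.449 ± 0.409 to 232 ± 72.2 CPM. The list passed camera at an adjusted p of 2.12e-25 with a preset correlation, with adjusted p = 0.209 with an estimated correlation and 0.00123 by fry. Of 12 M2-like genes 7 rose (9 adjusted over the list alone), with a median log2 fold change of 5.66. They included the mannose receptor Mrc1 (1.21 ± 0.817 to 85.6 ± 39.9 CPM), the scavenger receptors Cd163 (0.81 ± 0.104 to 14.4 ± 6.32 CPM) and Msr1, and Chil3. Chil3 had 6272, 596 and 224 counts in TKO1, TKO2 and TKO3. The M2-like list passed camera at 3.47e-06, with adjusted p = 0.209 with an estimated correlation. Of the 26 core macrophage genes 17 lay under 1 CPM in every DKO library. The rise of M2-like genes therefore does not show a change of macrophage state. MHC class II genes rose in 5 of 8 members (7 adjusted over the list alone; median 5.73, camera adjusted p = 2.77e-07, adjusted p = 0.209 with an estimated correlation), among them Cd74, the invariant chain, from 2.48 ± 1.09 to 227 ± 72.4 CPM, and H2-Ab1, from 3.85 ± 4 to 119 ± 57.8 CPM. The list levels of endothelial, pericyte, erythroid and skeletal muscle genes were also higher in every TKO library than in any DKO library. Not every member followed: 16 of 24, 6 of 13, 4 of 8 and 16 of 19 rose. The erythroid-list gene Tfrc, for one, had 153 ± 19.9 CPM in DKO and 211 ± 104 in TKO.

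The M1-like list did not pass camera (adjusted p = 0.732), and its members moved both ways. Of 16, 3 rose and 2 fell over all genes (4 and 4 adjusted over the list alone). The co-stimulatory receptor gene Cd86 rose (ratio 201, 55.3 to 1670), as did the formyl peptide receptor gene Fpr2 and Irf5. Nos2, the inducible nitric oxide synthase, fell from 349 ± 354 to 6.42 ± 5.3 CPM and Il12b from 10.9 ± 8.34 to 0.225 ± 0.267 CPM. The monocyte chemoattractants behaved likewise (camera adjusted p = 0.732), with 2 of 14 higher and 2 lower (5 and 3 adjusted over the list alone). Ccl6 and Cxcl12 rose by log2 fold changes of 9.65 (SE 1.43) and 2.17 (SE 0.4). Ccl2, the main monocyte attractant, fell by 3.98 on the log2 scale (SE 0.82), from 338 ± 155 to 21.4 ± 21.2 CPM, and Vegfa fell by 2.33 (SE 0.52). The DKO libraries held few leukocyte transcripts, with 0, 3 and 0 counts of the pan-leukocyte gene Ptprc in DKO1, DKO2 and DKO3. Which cells made Nos2, Il12b and Ccl2 there was not determined, so these falls do not show a change of macrophage state.

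Other leukocyte genes rose unevenly. Of 11 B and plasma cell markers 8 rose (9 adjusted over the list alone), with a median log2 fold change of 8.89 (6.4 with genes at their bound). Igkc, the kappa light chain, had a ratio of 3400 (609 to 134000) and Jchain, which joins IgA and IgM subunits, 1590 (286 to 63000), while Cd22 rose at least 91.3-fold. The list passed camera at 1.81e-09, with adjusted p = 0.209 with an estimated correlation. Few T and NK cell genes passed the count filter: 10 of 34 listed genes could be tested, 1 rose (3 adjusted over the list alone), and the list missed the threshold (adjusted p = 0.0565, median 1.29). The riser was Cd4, which macrophages can also express, at 7.6 ± 6.03 CPM in TKO. With DKO1, DKO2, DKO3 or TKO1 left out, 21 of its genes passed the count filter, 11 of them not tested with all libraries, and the list passed at adjusted p of 1.64e-05, 1.02e-06, 4.61e-06 and 9.45e-09. These became adjusted p = 0.587, 0.518, 0.532 and 0.205 with an estimated correlation. On the 10 genes tested in both, the median without TKO1 was 1.56. Of 10 neutrophil markers 4 rose and 1, Lcn2, fell (6 and 1 adjusted over the list alone), with S100a9 at least 120-fold, Ngp at least 32.8-fold and Csf3r at least 242-fold higher (median 6.93, 4.65 with bounds; camera adjusted p = 0.000161, adjusted p = 0.209 with an estimated correlation, 0.0655 with the counts of the other strand column). Of 13 dendritic cell markers 3 rose (5 adjusted over the list alone), including the integrin Itgax, at least 362-fold, and Clec4n (median 2.01, camera adjusted p = 0.00311, adjusted p = 0.258 with an estimated correlation; median 0.06 and adjusted p = 0.629 with genes near absent in either group left out). Only 3 mast cell genes could be tested, too few for a list test, and none of Hdc, Kit and Gata2 passed.

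Among regulators of immunity, 3 of 11 checkpoint genes rose (3 higher and 1 lower adjusted over the list alone): Lag3 from 1.79 ± 0.234 to 14.7 ± 3.45 CPM, Vsir from 13.6 ± 2.35 to 97.5 ± 57.2 CPM, and Cd86. Cd47, the signal that restrains phagocytosis, had 151 ± 19.5 CPM in TKO and 343 ± 87.9 in DKO (adjusted p = 0.064). The checkpoint list was borderline (median 0.53, camera adjusted p = 0.0495, adjusted p = 0.518 with an estimated correlation), and lost the call without TKO2 (0.238) or TKO3 (0.0586), with sex as a covariate (0.0643) and with the other strand column (0.0648). Of 16 complement genes 6 rose (8 higher and 2 lower adjusted over the list alone), led by the C1q genes and C5ar1, a leukocyte receptor for C5a, at least 482-fold higher (median 1.76, camera adjusted p = 0.0389, adjusted p = 0.68 with an estimated correlation, 0.123 without TKO2, 0.0726 with sex as a covariate). With genes near absent in either group left out, the complement median was -0.38 (adjusted p = 0.793). MHC class I genes lay lower in TKO as a list (median -0.89, camera adjusted p = 0.00078, adjusted p = 0.603 with an estimated correlation and 0.14 by fry). Its level was lowest in TKO1 (5.41, against 6.84 and 6.57 in TKO2 and TKO3), and the endothelial, erythroid and muscle list levels were higher in the same TKO libraries, by 4.97, 4.21 and 7.14 log2 units. Of its 17 members 1, H2-Q7, fell, from 460 ± 247 to 82 ± 22.5 CPM (4 lower adjusted over the list alone, with B2m at 1200 ± 266 against 3300 ± 737 CPM). H2-Q genes share sequence, and reads that match several places were left out, so these genes may be undercounted. None of 32 interferon-stimulated genes passed over all genes or adjusted over the list alone, with a list median of -0.01 and mean of 0 (camera direction lower, adjusted p = 0.561).

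Genes of vessels, blood, muscle and other normal tissues moved with the macrophage genes. Of 24 endothelial markers 16 rose (18 adjusted over the list alone; median log2 fold change 5.6), with VE-cadherin, Cdh5, going from 0.459 ± 0.0899 to 119 ± 85.5 CPM, Plvap from 4.35 ± 0.897 to 138 ± 79.9 CPM and the receptor gene Tie1 at a ratio of 1620 (449 to 13400). This list passed camera at 2.06e-13, with adjusted p = 0.251 with an estimated correlation. The endothelial gene Vwf, named after its values were seen, did not follow. It had 78.3, 4.39 and 43.8 CPM in DKO1, DKO2 and DKO3 and 8.34, 60.6 and 9.79 CPM in TKO1, TKO2 and TKO3. Of 13 pericyte and smooth muscle markers 6 rose (8 adjusted over the list alone; median 3.41, camera adjusted p = 0.000146, adjusted p = 0.305 with an estimated correlation), including Rgs5, at a ratio of 5130 (920 to 203000), Mcam, and Acta2, from 20.2 ± 1.22 to 215 ± 184 CPM. Skeletal muscle markers rose in 16 of 19 (18 adjusted over the list alone; median 8.5, camera adjusted p = 9.61e-13, adjusted p = 0.258 with an estimated correlation), among them titin, Ttn, from 5.04 ± 1.68 to 327 ± 258 CPM, and Eno3, from 10.5 ± 1.99 to 185 ± 104 CPM. Of 8 erythroid genes 4 rose (5 adjusted over the list alone; median 3.47, camera adjusted p = 0.000776, adjusted p = 0.25 with an estimated correlation): Hba-a1, Hbb-bs, Hbb-bt and the haem synthesis gene Alas2. Summed haemoglobin genes had 12 counts over the 3 DKO libraries and 37868 over the 3 TKO libraries. Skin and epithelial markers rose in 3 of 7 (3 adjusted over the list alone; median 5.05, camera adjusted p = 0.00546, adjusted p = 0.209 with an estimated correlation), with Lor, Cdh1 and Epcam at 1.39 ± 0.23, 7.63 ± 4.64 and 2.39 ± 1.89 CPM in TKO. Its median was 0.87 without TKO1, in which Krt18 had 13031 counts against 35 and 6 in TKO2 and TKO3, and its call was lost with the other strand column (0.113). No adipocyte gene of 8 passed over all genes (4 higher adjusted over the list alone; median 1.21, camera adjusted p = 0.0305, adjusted p = 0.25 with an estimated correlation), with Pparg at 15.2 ± 12.2 CPM in TKO and 0.91 ± 0.592 in DKO (adjusted p = 0.0512). The adipocyte call was lost with at least 1 CPM in 3 samples (0.179), sex as a covariate (0.0629) and the other strand column (0.0658).

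**Figure D2:**
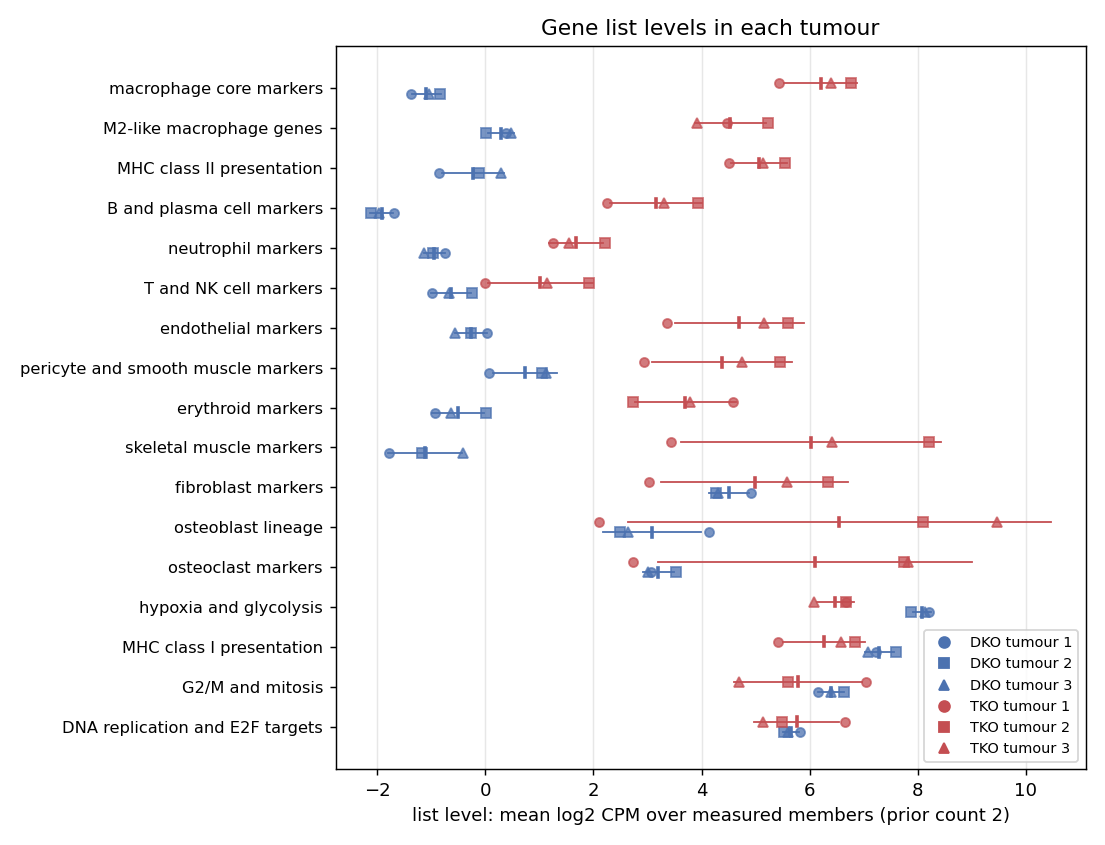
Level of 17 gene lists in each tumour, as the mean log2 CPM over measured members (prior count 2), with the group mean as a vertical bar and its SD as a horizontal line (n = 3). Macrophage, endothelial and muscle lists lie higher in every TKO tumour than in any DKO tumour, hypoxia and glycolysis genes lie lower, and TKO1 lies apart from TKO2 and TKO3 in the osteoblast and osteoclast lists.

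Secreted stress, matrix and metabolic genes were among the largest decreases in TKO, beside genes of other kinds. These kinds were read from the named genes and were not tested. Saa3, an acute-phase serum amyloid (chromosome 7, 46711998 to 46715700), fell 458-fold, from 2910 ± 2800 to 6.34 ± 9.14 CPM (log2 fold change -8.84, SE 1.72, adjusted p = 0.0333). Lcn2, a siderophore-binding lipocalin (chromosome 2, 32384633 to 32388252), fell 266-fold, from 897 ± 567 to 3.36 ± 2.74 CPM (adjusted p = 0.0131). The stromelysin Mmp3 fell 235-fold from 2520 ± 1720 to 10.7 ± 14 CPM, and Grem1, a secreted antagonist of bone morphogenetic proteins, 207-fold from 845 ± 499 to 4.08 ± 3.49 CPM. Sh2d6 fell 417-fold, with the smallest p of this group (adjusted p = 0.0111). The metabolic stress hormone Fgf21 fell 303-fold, the protease inhibitor Serpina3m 265-fold, the carbonic anhydrase Car6 206-fold, Snhg11 147-fold, the vasoactive peptide gene Adm2 127-fold and the glutamate transporter Slc1a2 91.4-fold, the last at an adjusted p of 0.0488. Fgf21 had 11, 0 and 0 counts in TKO1, TKO2 and TKO3, and its log2 fold change ranged from -12.94 to -6.81 over the settings tried. The calls of Fgf21 and Slc1a2 were lost in 8 of 17 settings, and those of Saa3, Mmp3, Grem1 and Snhg11 in 8 of 18. Serpina3m belongs to a tandem family with similar sequence. As lists, macrophage, endothelial, erythroid and muscle genes had higher levels in the same TKO libraries, by 7.29, 4.97, 4.21 and 7.14 log2 units.

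Hypoxia and glycolysis genes fell as a list. Of 23 members 6 fell and none rose (14 lower adjusted over the list alone), with a median log2 fold change of -1.48. The list level was 6.47 ± 0.34 in TKO and 8.08 ± 0.17 in DKO (exact two-sided permutation p = 0.1, the smallest possible), and all 3 TKO tumours, TKO1 included, lay below every DKO tumour. The mitophagy receptor Bnip3 fell from 112 ± 28.9 to 17.1 ± 2.75 CPM, Adm from 40.3 ± 14.1 to 4.07 ± 0.925 CPM, hexokinase 2, Hk2, from 170 ± 39.7 to 40.7 ± 17.9 CPM, and the glucose transporter Slc2a1 from 318 ± 56.9 to 44 ± 28.5 CPM. The list passed camera at 6.64e-08 and fry at 0.00822, with adjusted p = 0.209 with an estimated correlation. In the same TKO libraries the macrophage, endothelial, erythroid and muscle list levels were higher, by 7.29, 4.97, 4.21 and 7.14 log2 units.

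Smaller decreases were found in 3 other lists, each lost by fry. The list levels of macrophage, endothelial, erythroid and muscle genes were higher in the same TKO libraries. Of 17 immediate early and heat shock genes 3 fell (3 adjusted over the list alone): Ier3 from 345 ± 44.7 to 21 ± 10.6 CPM, Egr1 from 246 ± 64.1 to 40.7 ± 10 CPM and Atf3 from 47 ± 6.66 to 9.51 ± 1.78 CPM. The list median was -0.07 (camera adjusted p = 0.0408, adjusted p = 0.631 with an estimated correlation, 0.117 by fry), and the call was lost without DKO2 (0.115), TKO2 (0.0509) or TKO3 (0.203) and with sex as a covariate (0.063). Without TKO1 the median was -1.11. Of 34 matrix remodelling genes 2 fell (2 adjusted over the list alone), Mmp3 and the fibronectin receptor subunit Itga5, from 657 ± 234 to 185 ± 41.9 CPM. That list had a median of -0.1 (camera adjusted p = 0.0408, adjusted p = 0.68 with an estimated correlation, 0.452 by fry) and lost its call without DKO1 (0.0866), TKO1 (0.46) or TKO3 (0.0872), where the median without TKO1 was 0.12 and without DKO1 0.04. None of 12 mitochondrially encoded genes passed (none adjusted over the list alone), with a median of -0.64 (camera adjusted p = 0.0322, adjusted p = 0.68 with an estimated correlation, 0.429 by fry), lost without DKO1 (0.206) or TKO1 (0.255). The gene mt-Co1 had 6990 ± 3070 CPM in TKO and 14900 ± 1550 in DKO.

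With all 6 libraries, no gene closest to SKP2 function passed the test at the transcript level. SKP2 targets proteins for degradation, so transcript counts do not show whether its substrates changed as proteins. The test also recovered only 10% of simulated 4-fold changes, in genes drawn at random among those of at least 1 CPM. The SE of the 20 SKP2 partners and substrates ran from 0.23 to 1.42, so this share does not hold alike for each of them. None of 20 SKP2 partners and substrates passed over all genes or adjusted over the list alone, and the list median of 0.16 and mean of 0.15 had a sign opposite to the camera direction (lower, adjusted p = 0.994). Without TKO1, 1 of them was lower and the median was -0.16 (adjusted p = 0.276). Cul1, the SCF scaffold, had 206 ± 73.5 CPM in TKO and 118 ± 55 in DKO (adjusted p = 0.302), and the substrate Rbl2 37.3 ± 11.2 against 21.6 ± 4.6 CPM (adjusted p = 0.215). None of 34 DNA replication and E2F targets passed either way of adjusting (median 0.25, camera adjusted p = 0.905), with Ccne2 at 86.5 ± 63.7 CPM in TKO and 27 ± 9.99 in DKO. This list reversed without TKO1 (median -0.37, adjusted p = 0.019, adjusted p = 0.502 with an estimated correlation). Mitotic genes were lower as a list although none of 28 passed over all genes or adjusted over the list alone (median -0.32, camera adjusted p = 0.00969, adjusted p = 0.765 with an estimated correlation, 0.536 by fry). Bub1, a spindle checkpoint kinase, had 29 ± 11.4 CPM in TKO and 61.8 ± 4.74 in DKO (adjusted p = 0.114), and Hmmr 37.7 ± 22.2 against 107 ± 27.2 CPM (adjusted p = 0.127). TKO1 lay on the other side: its G2/M level was 7.04, above all DKO tumours (6.15, 6.64 and 6.4), while TKO2 and TKO3 had 5.6 and 4.69. Without TKO1, 10 G2/M genes fell and the median was -1.24 (adjusted p = 1.48e-08, adjusted p = 0.391 with an estimated correlation), whereas the call was lost without TKO2 (0.0692) or TKO3 (0.57, median 0.04).

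With all 6 libraries, the apoptosis, p53 and growth lists did not pass camera. Of 18 genes of E2F1-linked apoptosis 2 rose (3 adjusted over the list alone), among them the BH3-only gene Bmf, from 2.59 ± 0.897 to 24.9 ± 7.3 CPM. The list passed fry (0.00537) but not camera (adjusted p = 0.257), with a median of 0.3. Of 24 p53 targets, in tumours built to lack p53, 2 rose and 4 fell (4 and 5 adjusted over the list alone), with Trp53i11 and Sesn1 higher and Sesn2, Fas, Plk2 and Gadd45a lower. Their median of 0.19 and mean of 0.15 lay opposite to the camera direction (lower, adjusted p = 0.905). Among 34 MYC targets and 34 cytosolic ribosomal protein genes none passed over all genes or adjusted over the list alone, with medians of 0.04 and -0.04 (camera adjusted p = 0.562 for both). The MYC mean was -0.01 with a camera direction of lower, and without TKO1 that list passed (median -0.2, adjusted p = 0.046, adjusted p = 0.445 with an estimated correlation). Over the settings tried the ribosomal median lay between -0.22 and 0.11 and the MYC median between -0.2 and 0.12.

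The osteoblast and osteoclast list levels were higher in TKO2 and TKO3 than in every DKO tumour, and lower in TKO1. Of 18 osteoblast genes 3 rose (5 adjusted over the list alone; median 5.28): Dmp1, Phex, a phosphate regulator of osteocytes, from 0.477 ± 0.287 to 87.3 ± 109 CPM, and Omd, from 0.305 ± 0.369 to 89 ± 72.5 CPM. These 3 were higher in TKO1 too than in any DKO library, with 393 counts of Dmp1, 1076 of Phex, above the 133 in TKO2, and 130 of Omd. The list levels were 2.1, 8.09 and 9.46 in TKO1, TKO2 and TKO3 and 4.13, 2.49 and 2.63 in the DKO tumours (exact two-sided permutation p = 0.4). Camera gave an adjusted p of 0.00813, with adjusted p = 0.68 with an estimated correlation, 0.319 by fry and 0.118 without TKO3, and 10 osteoblast genes rose without TKO1. Osteoclast genes had the same pattern: 1 of 15, the tartrate-resistant phosphatase Acp5, rose over all genes (8 adjusted over the list alone; median 4.24), and 12 rose without TKO1. Their levels were 2.74, 7.75 and 7.81 in TKO1, TKO2 and TKO3 against 3.06, 3.53 and 3 in DKO (exact two-sided permutation p = 0.4; camera adjusted p = 0.00751, adjusted p = 0.68 with an estimated correlation, 0.319 by fry, 0.0692 without TKO2 and 0.0674 without TKO3). Acp5 had 31.5, 1300 and 1850 CPM in TKO1, TKO2 and TKO3 and at most 1.63 CPM in DKO. Of 10 chondrocyte genes 1, Comp, rose (3 adjusted over the list alone; median 2.87, camera adjusted p = 0.145), and the list passed without DKO2 (0.0332), DKO3 (0.0412) or TKO1 (1.14e-05). With an estimated correlation these became adjusted p = 0.657, 0.688 and 0.174. These tests used 14 genes, 4 of them not tested with all libraries, and on the 10 genes tested in both the median without TKO1 was 2.93. None of 18 fibroblast genes passed over all genes or adjusted over the list alone (median 0.96, camera adjusted p = 0.707; 5 rose without TKO1), with Fap at 173 ± 216 CPM in TKO and 4.42 ± 3.97 in DKO (adjusted p = 0.0816).

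**Figure D3:**
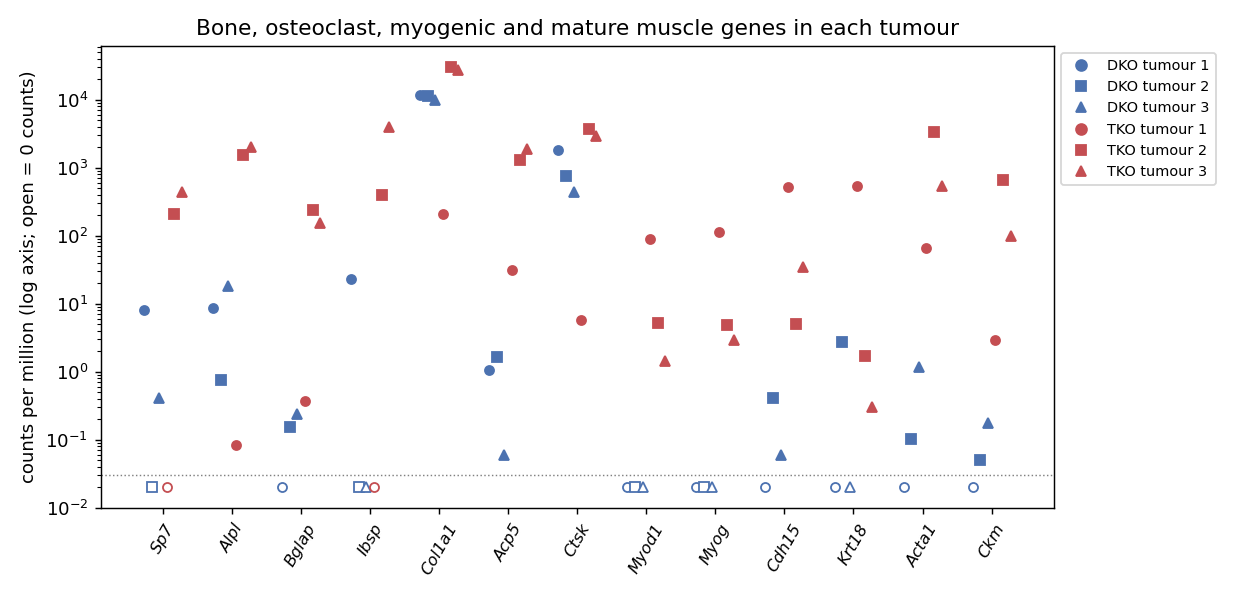
Counts-per-million (log axis) of bone, osteoclast, myogenic and mature muscle genes in each tumour, chosen after their values were seen, with open symbols below the dotted line for 0 counts. TKO1 has 209 CPM of Col1a1 against 30200 and 26900 in TKO2 and TKO3, and 90.5 CPM of Myod1 against 5.26 and 1.43.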

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

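The tests of muscle content and of the library's labels below were chosen after the values were seen, while the bound for the progenitor genes was set before they were measured. In 8 lists the male contrast, TKO1 against DKO1, ran opposite to that of the females, in which both TKO tumours lay on one side of both DKO tumours. The list level differences were 0.59 in the male and -0.26 in females for SKP2 partners and substrates, 0.88 and -1.37 for G2/M genes, 0.83 and -0.26 for DNA replication and E2F targets, and 0.24 and -0.18 for MYC targets. They were -0.88 and 0.52 for M1-like genes, -1.9 and 1.67 for fibroblast genes, -2.03 and 6.22 for osteoblast genes and -0.32 and 4.52 for osteoclast genes. The difference between the sexes was not tested, since each group has 1 male, so sex and tumour cannot be separated here. The share of reads that fell in more than 1 gene was also higher in TKO, with a lowest TKO value of 5.87% against a highest DKO value of 5.54%.

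In TKO1, several bone genes were low and regulators of muscle development were high. Col1a1 had 209 CPM in TKO1, against 30200 and 26900 in TKO2 and TKO3 and 11800, 11200 and 9950 in DKO1, DKO2 and DKO3. Sp7 had 0 counts and Alpl 2 in TKO1, against 4280 and 31634 in TKO2 and 8501 and 40108 in TKO3, but both were low in DKO as well, with 160, 0 and 7 counts of Sp7 and 176, 15 and 304 of Alpl. Phex, with 1076 counts in TKO1 and 133 in TKO2, went the other way. Myod1 and Myog, the transcription factors that commit cells to muscle, had 2172 and 2763 counts in TKO1, 109 and 102 in TKO2, 28 and 58 in TKO3 and 0 in all DKO libraries. All 8 genes of a muscle development list, drawn up after they were seen, were higher in TKO1 than in TKO2 and TKO3, by a median of 5.04 log2 units. Beside Myod1 and Myog the list held Mymk, Cdh15, Musk, Dok7, Chrnd and Chrng, which are not transcription factor genes. These genes were chosen after their values were seen.

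Mature muscle was argued against as the source of the high Myod1 and Myog counts in TKO1. The mature muscle list of TKO1 lay 3.86 log2 units below the mean of TKO2 and TKO3 (a difference of -3.86). Its level of 3.44 was still above -1.78, -1.17 and -0.42 in DKO1, DKO2 and DKO3, so muscle RNA in the sample was not excluded. The test covered mature muscle genes only. Deletion of Rb1 and Trp53 in TKO1 was not checked by these gene-level counts, and Rb1 had 91.7 CPM in TKO1 against 21.3 in DKO1. A library of another Skp2 genotype or of another sex was also argued against: TKO1 had 0 Skp2 counts, 3 Xist counts and 442 counts over 4 Y-linked genes. Those Y-linked genes were nevertheless lower than in the other male tumour, at 0.0619 to 0.0936 of the DKO1 CPM, with Ddx3y at 198 counts against 1902, and the reason was not tested. A candidate explanation that stays open is a tumour with cells of a myogenic kind. In 12 progenitor genes not looked at before, the median was 0.72 log2 units higher in TKO1 than in TKO2 and TKO3, between the bounds of 2 and 0 set beforehand, so the test left the question undecided. The effect of Skp2 loss on tumour type stays open and untested, as 1 of 3 TKO tumours shows the pattern.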

How the results depend on the processing

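The restriction to genes with at least 1 CPM in a library of each group was chosen after seeing the data. The count of 1131 genes stayed within 1.5 times under RLE factors, library totals, limma-voom, no filter, a stricter filter, sex as a covariate, the other strand column, no robust fitting, leaving out muscle, erythroid and mitochondrial genes, and a log2 fold threshold of 1 (1021 to 1280 genes). DESeq2 called 3103 (2066 higher, 1037 lower), with 90.4 false calls per run on simulated data against 4.8. Genes with 1 CPM in both groups gave 158 (74 higher, 84 lower) and 10 lists (7 higher, 3 lower), and the complement median became -0.38. Of the 1131 genes 561 were tested there and 403 lost their call. Adjusting the p-values of the full test over the same genes, without a new fit, gave 149, so the adjustment accounts for the loss (median p of the 561 was 0.00143, and 0.00138 in the new fit). Dendritic (0.629), checkpoint (0.0866), osteoblast (0.0751), matrix (0.0751), immediate early (0.0683), adipocyte (0.107) and mitochondrial (0.0633) lists also missed the threshold there. The replicate block gave 295 genes (212 higher, 83 lower), but the numbers do not pair the tumours: deviations of same-numbered tumours correlated across genes at -0.01, 0.01 and -0.02, and not every tumour correlated best with its own number. Under the block the checkpoint, complement and immediate early lists missed the threshold (adjusted p = 0.0836, 0.0684 and 0.0596). Leaving out a library gave 0 to 2385 genes, 0 to 1575 higher and 0 to 810 lower, and 3 to 6 lists lower. The DNA replication and E2F median ranged from -0.37 without TKO1 to 0.45 without TKO3. With an estimated correlation 0 lists passed (0 higher, 0 lower), also without any 1 library, and fry called 1 list lower. The difference in macrophage list level was 7.29, and 8.23 with a prior count of 0.5, since a smaller prior count pulls genes near 0 less, or 7.93 with the median of members; without single libraries it was 7.01 to 7.67. Directions of Skp2, Rb1, Trp53, the 12 highest and 12 lowest genes and the lists that passed held in every setting that tested them, apart from complement components, and other named genes were not tried; matrix remodelling and G2/M genes kept the camera direction while their medians reached 0.12 and 0.04. Causes not stated here were not tested. Depth limits genes at a few counts, such as most T cell genes.

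Of the 10 splits of the 6 libraries into 3 and 3, 1 gave 1131 or more genes (the real split, highest other 0) and 1 gave 22 or more lists (the real split, highest other 20). With 10 splits no share can fall under 0.05. Every other split puts both genotypes on each side, so the difference between genotypes enters its spread. The 0 genes there therefore do not measure chance. A mixed split gave 20 lists, so the number of lists barely sets the real split apart.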

Other observations

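The tests of cell type content below were chosen after the values were seen, while the bound for the sterol genes was set before they were measured. Genes of cholesterol synthesis lay lower in TKO tumours. The synthesis enzymes Sqle and Hmgcs1 were among the genes noticed first, with Sqle at 339, 203 and 374 CPM in the DKO tumours and 84.8, 32.5 and 29.8 CPM in the TKO tumours. A list of 20 other sterol genes was then fixed and measured. Its median log2 fold change was -1.54, past the bound of -1 set beforehand, with 5 genes lower and 0 higher over all genes by edgeR (camera adjusted p = 8.9e-08, adjusted p = 0.202 with an estimated correlation). The 5 were the lanosterol synthase Lss, fallen by 2.11 on the log2 scale (SE 0.38), Fdft1, Dhcr7, Insig1 and Acat2. TKO1 stood apart, with 17 of the 20 genes higher than in both TKO2 and TKO3, by a median of 1.08 log2 units over their mean. Macrophage, endothelial, erythroid and muscle list levels were higher in the same TKO libraries, by 7.29, 4.97, 4.21 and 7.14 log2 units. No edgeR call held without DKO3, where 0 genes passed (3017 at an unadjusted p under 0.05; 2203 by DESeq2).

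Some inflammatory genes, chosen after their values were seen, were expressed in tumours with few transcripts of Ptprc, the pan-leukocyte gene. It had 0, 3 and 0 counts in DKO1, DKO2 and DKO3 and 501, 1971 and 1732 in TKO1, TKO2 and TKO3. In the DKO tumours Saa3 reached 6130, 1600 and 992 CPM, and Ccl2 and Nos2 averaged 338 ± 155 and 349 ± 354 CPM (SD, n = 3). The M1-like and chemoattractant lists as a whole did not pass (camera adjusted p = 0.732 for each), and Ccl6 and Fpr2 were higher in TKO.

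Most core macrophage genes were near 0 in DKO, and the level of their list was higher in every TKO library. Some leukocyte genes did not follow: Cd68 had 110, 2385 and 1529 counts in DKO1, DKO2 and DKO3, and Cd3e 2, 5 and 4 in TKO1, TKO2 and TKO3. Swapped group labels were argued against, as the lowest Skp2 count in DKO was 20 and all TKO libraries had 0. A difference in leukocyte number alone, with vessels and blood alike, was also argued against: the endothelial median log2 fold change was 5.6 with genes at 0 set to their bound, and haemoglobin genes summed to 0, 7 and 5 counts in DKO1, DKO2 and DKO3 against 27474, 1761 and 8633 in TKO1, TKO2 and TKO3. What stays open is that the DKO libraries may hold little RNA of any cell type other than tumour cells. The smallest median over the endothelial, pericyte, erythroid and muscle lists was 3.41. In DKO1, DKO2 and DKO3, Ptprc had 0, 3 and 0 counts, Pecam1 0, 8 and 9, and C1qa 0, 0 and 0. With the haemoglobin counts, these values argue against DKO tissue sampled with its blood, vessels and leukocytes, for these genes. Some genes went the other way, such as Cd68, Vwf (1572, 86 and 738 counts) and Kdr (113, 38 and 80). How the DKO samples came to hold so little of this RNA was not tested. Of the 26 macrophage genes 17 lay under 1 CPM in every DKO library and 3 are in another list, and of the 24 endothelial genes 14 and 1. An effect of Skp2 loss on macrophage entry stays open and untested, because genotype and this broader difference fall on the same samples, and the labels describe fresh tumour tissue for both groups. The codes in the sample titles end in R for every DKO tumour and in T for every TKO tumour, and what these letters stand for is not given in the sources used here.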
